A study of Mus musculus with 4 samples.

How the data were processed

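Whole exomes were sequenced from 4 lung DNA libraries of mice, with 1 library in each of 4 groups: normal lung and lung tumor of the wild type (WT), and normal lung and lung tumor of a knock-in that carries the FEN1 A159V change on 1 allele. FEN1, flap endonuclease 1, trims the 5' flaps of Okazaki fragments so that lagging-strand DNA can be joined. Per the labels' protocols, DNA was extracted with proteinase K and phenol/chloroform and exons were captured before library preparation. The labels do not say whether the tumor and the normal lung of a genotype came from the same animal. Groups were taken from the sample titles, and each column of the 2 tables was matched to its sample through the column name given in that sample's description. No column of per-sample values was left unused.

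Each genotype had 1 table of tandem duplication calls with a tumor and a normal column. Per the file headers, the calls were made with Pindel, a split-read caller, on GRCm38. The submitters' processing notes also name BWA, an aligner, and list mm10 beside GRCm38; versions of Pindel and BWA are not given in the sources used here. Per the file headers, the values used here are the deposited counts of reads that support the reference allele and the duplicated allele, and they were used as deposited, with no normalization. Filters applied before deposit are not given in the sources used here. All 1404 records were marked as passing, all were tandem duplications, and all had a breakpoint homology of 0 bp. The length of the altered allele minus that of the reference allele equalled the duplicated length plus the number of intervening bases in all 1404 records, and every inserted sequence ended with the duplicated segment. Here the duplicated length is the reported length of the segment, and intervening bases are the other inserted bases, which lie between the copies. Coordinates are on GRCm38, and each start is the base before the duplicated segment.

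A duplication was counted as a call in a library when at least 1 read supported it there. Genes were assigned by overlap with gene spans in the RefSeq table of the same assembly, which holds 49997 genes, 21900 of them protein-coding. That table gives spans without exons, so the planned share in coding sequence was computed as the share in protein-coding gene spans, and exons, introns and untranslated regions were not told apart. A record was called repetitive when the reference allele held a homopolymer of at least 8 bp, or at least 3 copies of a unit of up to 6 bp over at least 12 bp. Windows of 100 kb with at least 8 records over both tables are called dense windows. Major satellite, the tandem repeat of mouse pericentromeres, was recognised by at least 2 shared 12-mers with its consensus. Records within 10 bp of each other were treated as 1 locus. Intervening bases of at least 20 bp outside repetitive records were searched for 12-mers of the duplicated segment and of its reverse complement.

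With 1 library per group there is no replicate check of any difference and no test between groups. Counts carry exact Poisson intervals, ratios of counts exact conditional binomial intervals, and shares exact Clopper-Pearson intervals, all at 95%. For the tumor to normal ratio, calls seen in both libraries were left out. The 2 ratios of tumor to normal calls were compared by an exact conditional odds ratio. Medians carry intervals from order statistics, and mean log2 depth ratios carry intervals over sites. Depth ratios used reference reads plus 1 at loci with at least 40 reference reads summed over both libraries of a genotype, or over all 4 between genotypes, a limit chosen after the data were seen; between genotypes, limits of 0, 1, 10 and 20 were also run. Satellite depth ratios between genotypes used single start positions recorded in both, not merged into loci. Where a library had no supporting read, the limit given is 3 reads of its depth. Intervals and limits cover counting error only, since reads without molecular identifiers can be copies of 1 molecule. At each site Fisher's exact test, two-sided, compared duplicated and reference reads of the tumor and the normal library, with Benjamini-Hochberg adjustment over all 1404 sites and a threshold of 0.05; it compares 2 libraries, not conditions.

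The named genes followed a rule. It took members of the lung cancer, replication and DNA repair lists with a call, at most 12 per list by most supporting reads. Per genotype it took, in protein-coding gene spans, the 6 duplications with most tumor reads and none in normal lung. From such spans also came the 4 with most normal reads and none in the tumor, and the 4 longest duplications. Per genotype the rule further took the 4 sites in any place with the smallest Fisher p, and the 4 genes with most records. It also took up to 6 variants found in both tables, and Fen1 whatever its value. Ties went to the site with more reference reads, and ties between genes to alphabetical order. Groups, tests, this rule, 9 gene lists and most alternative settings were fixed before the data were examined. The lists cover lung cancer, replication, DNA repair, apoptosis and cell cycle, RAS, MAPK and PI3K signalling, chromatin, polyglutamine repeats, large genes, and lung epithelium with secreted products; prefixes of multigene families formed a separate set for 1 alternative. Alternatives changed the read support to 2, 3 or 5 reads, the depth to 20 reads in both libraries, the variant read fraction to 0.10, the kinds of record counted and the scaling for depth.

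Over the records of each genotype, the supporting and reference reads at listed sites came to 96219 in WT normal lung, 162406 in WT tumor, 70412 in A159V normal lung and 105529 in A159V tumor. These totals cover each genotype's own sites and are not library totals. The median depth per site was 1 read in WT normal lung, 2 in WT tumor, 1.5 in A159V normal lung and 2 in A159V tumor, so most single sites carry wide intervals. The per-site test was tested on simulated reads at the real depths of 755 sites. With 50% of tumor reads duplicated at planted sites and 1% elsewhere, it recovered 82 of 82 planted sites at depths of at least 20 reads, 17 of 118 at lower depths, and none of 555 other sites. The gene assignment found 200 of 200 simulated points in their gene. The search for copies found 67 of 67 planted second copies, 66 of 66 planted reverse complements, and none in 67 sequences without one. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.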

Results

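The data were 2 tables of tandem duplications from exome sequencing of lung, 1 for the wild type and 1 for the FEN1 A159V heterozygote, each with read counts for a tumor and a normal library. There were 792 WT records and 612 A159V records. Most of them rested on very few reads: 699 WT records (88.3%) and 549 A159V records (89.7%) had 1 supporting read over both libraries. Most sites lay outside well-covered regions, and 171 WT and 124 A159V records had at least 20 reads in both libraries of the genotype. The genotype field gave the duplication to a library in 4 WT and 4 A159V records and called the reference in all others. Fen1, the gene that was altered (chromosome 19, 10199132 to 10204393), held no record in either table.

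The first question, set by the design, was how often duplications occurred in each genotype and tissue. The WT tumor carried the most calls, 502 (95% interval 459 to 548). WT normal lung had 339 (304 to 377), A159V normal lung 315 (281 to 352) and A159V tumor 334 (299 to 372). The A159V tumor thus had 0.665 times as many calls as the WT tumor (0.578 to 0.766), whereas the normal lungs differed by less than counting error, with a ratio of 0.929 (0.795 to 1.09). The lower count in the A159V tumor held in protein-coding gene spans, with 177 calls against 253, a ratio of 0.70 (0.574 to 0.851), and also for genes with a call, 158 against 219. At 2 or more reads the counts were 26 and 63 in WT normal lung and tumor, and 23 and 34 in A159V normal lung and tumor. Division by the reads summed over each genotype's own recorded sites gave 1.02 (0.889 to 1.18) for tumor and 1.27 (1.09 to 1.48) for normal lung, and outside dense windows 0.631 (0.541 to 0.735) and 0.731 (0.619 to 0.864). These sites differ in number and place between the genotypes, so the sums do not measure relative depth; at the 15 of 71 loci called in both that had at least 40 reference reads over the 4 libraries, outside dense windows and satellite, the median A159V to WT depth ratio was 0.941 (0.792 to 1.19) in tumor and 1.19 (0.941 to 1.40) in normal lung. At limits of 10 and 20 reference reads (22 and 19 loci) the median depth ratio was 1.00 in normal lung. In tumor it was 0.901 and 0.941. At limits of 0 and 1 (71 and 52 loci) it was 1.00 in both tissues. Most of those loci had fewer than 10 reference reads over the 4 libraries, and the added 1 draws such ratios to 1. The 2 lowest limits thus say little about depth. Each group was 1 library, so differences between animals were not measured.

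**Figure D1:**
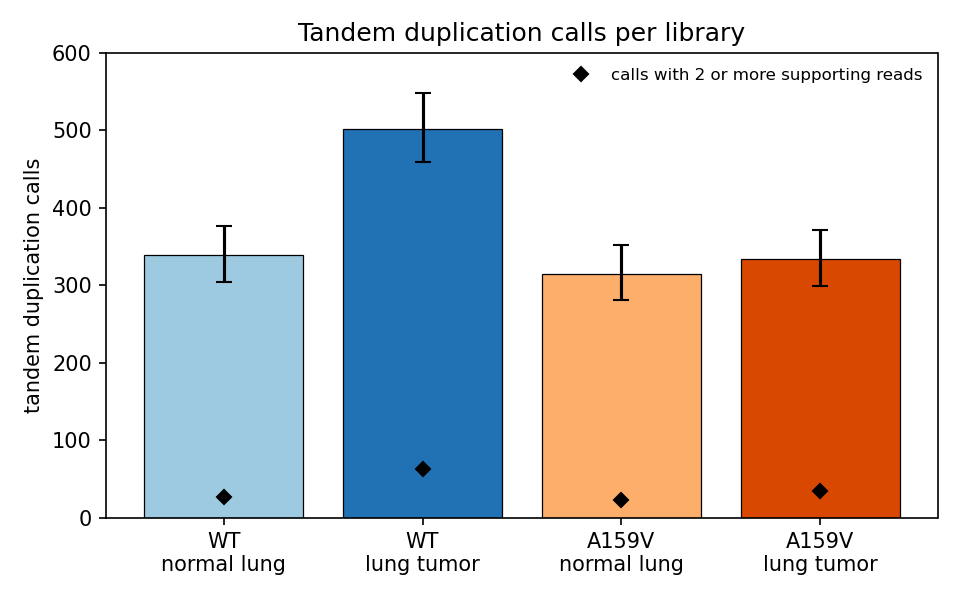
Tandem duplication calls (vertical axis, number of calls with at least 1 supporting read) in the 4 libraries, with exact Poisson 95% intervals as error bars and diamonds for calls with 2 or more reads. The WT tumor stands at 502 calls and the other libraries lie between 315 and 339; with 2 or more reads the counts fall to between 23 and 63.

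The second comparison set each tumor against normal lung of its genotype. In the WT, 453 calls were seen in the tumor alone and 290 in normal lung alone, a ratio of 1.56 (1.35 to 1.82). In A159V the numbers were 297 and 278, a ratio of 1.07 (0.904 to 1.26). The A159V ratio was 0.684 times the WT ratio (0.545 to 0.858, exact conditional interval). In the WT, 49 records (6.19%) had reads in both libraries, and in A159V 37 (6.05%). Division by reads at the recorded sites turned the WT ratio to 0.925 (0.797 to 1.08) and gave 0.713 (0.603 to 0.843) for A159V. Without dense windows the A159V ratio was 0.672 times the WT ratio (0.528 to 0.854), and 0.832 times (0.654 to 1.06) when also scaled by reads outside them.

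Among WT duplications in protein-coding gene spans with reads in the tumor and none in normal lung, the best supported lay in Fgfr2, a fibroblast growth factor receptor (chromosome 7, 130218652 to 130218681), with 5 of 5 tumor reads and a normal depth of 0. Zscan18, a zinc finger gene, had 3 of 135 tumor reads (2.22%, 0.461 to 6.36) and none of 98 normal reads, which allows up to 3.06%. Sucla2, a subunit of mitochondrial succinyl-CoA ligase, had 3 of 3 tumor reads and a normal depth of 0. Of those with 2 tumor reads, the 3 with most reference reads were 2 records in Chl1, which encodes a neural cell adhesion molecule, and 1 in Zfp534. In protein-coding gene spans the A159V tumor held none with more than 2 reads. The 6 with most reference reads were led by Chl1 (2 of 351 reads), Zfp984 (2 of 85) and Vcpkmt (2 of 31). Mov10l1 (2 of 26), Slc11a2 (2 of 20) and Npas1 (2 of 3) followed. Normal depths there were 271, 109, 31, 19, 13 and 2 reads in the same order. The Chl1 records lay within 10 bp of others with reads in normal lung of the same genotype. The WT Zscan18 record overlapped another WT record, from 12774606, with 3 normal reads. WT normal lung had reads within 10 bp of the A159V records in Zfp984, Npas1 and Mov10l1. A159V normal lung had reads within 10 bp of the WT records in Fgfr2, Sucla2 and Zscan18. Outside genes, a satellite position on chromosome 2 (98666984 to 98667033) had 5 of 2150 A159V tumor reads (0.233%, 0.0756 to 0.542) and none of 1268 normal reads, which allows up to 0.237%.

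In protein-coding gene spans, duplications seen in normal lung alone were led in A159V by Cmya5, which encodes a large muscle protein (chromosome 13, 93096891 to 93096937). It had 8 of 92 normal reads (8.70%, 3.83 to 16.4) and none of 61 tumor reads, which allows up to 4.92%. Slc6a13, a transporter of the neurotransmitter GABA, followed with 4 of 4 normal reads, and C2cd2l and Agmo with 3 of 3 each, but tumor depth was 1, 2 and 0 reads there, too low to show absence. In the WT the list held Rpap3 (3 of 18 normal reads), Mov10l1 (2 of 21), Fbxo34 (2 of 3) and Map3k2 (2 of 2), at tumor depths of 15, 13, 2 and 0 reads. The Rpap3 and Slc6a13 records lay within 10 bp of others with tumor reads in the same genotype. WT tumor had reads within 10 bp of the A159V records in Cmya5 (1 of 55), Slc6a13 (10 of 12) and C2cd2l (2 of 4). A159V tumor had reads within 10 bp of the WT records in Rpap3, Map3k2 and Mov10l1. The Agmo and Fbxo34 loci had no record in the other genotype. Mov10l1 was thus seen in normal lung of the WT and in the tumor of A159V, at the same position, 89011982 to 89012023 on chromosome 15.

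No site passed the threshold between tumor and normal lung after Benjamini-Hochberg adjustment of Fisher's exact test over 1404 sites, and the smallest adjusted p was 1. For most sites this outcome was fixed in advance, since 1248 of the 1404 records had 1 supporting read over both libraries. A single read cannot give a small p unless the depths of the 2 libraries are very unlike. Without adjustment 2 sites lay under 0.05. Irak4, a kinase of interleukin-1 and Toll-like receptor signalling, had 14 of 20 WT tumor reads and 4 of 15 WT normal reads (exact p = 0.0176, adjusted p = 1). Cmya5 in A159V had an exact p of 0.0220 (adjusted p = 1). The next WT sites were a satellite position on chromosome 9 (3037362 to 3037411), Tmem245 and Zfp534; in A159V they were C2cd2l and satellite positions on chromosomes 14 and 2. At depths below 20 reads the simulation recovered 17 of 118 planted sites, so at most sites even large differences were mostly not detectable. Its full recovery at deeper sites was for many large planted differences, so smaller or rarer ones may be missed there too. The simulation drew reads anew and did not keep the low numbers of supporting reads in the records.

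Duplicated segments had the same median length and quartiles in both genotypes. The median was 41 bp (39 to 42) in the WT, with quartiles of 34 and 46 bp, and 41 bp (40 to 42) in A159V, with the same quartiles. The range was 17 to 49 bp in the WT and 19 to 49 bp in A159V, so no record fell into the classes of 1 to 10 bp or over 100 bp. Segments of 11 to 30 bp made up 13.8% of WT records (11.4 to 16.4) and 16.0% of A159V records (13.2 to 19.2), and the rest were 31 to 49 bp long. The counts rose towards 49 bp and then stopped, as did the intervening bases at 69 bp. The longest duplications in gene spans were all 49 bp. In the WT these were in Ms4a6d, Vmn1r128, a vomeronasal receptor gene, Ticrr and Ap2a2, and in A159V in Vipr1, Spn, 1700018F24Rik and Unc79, each with 1 supporting read.

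Few records were plain tandem copies. Exact copies with no intervening bases made up 90 WT records (11.4%, 9.24 to 13.8) and 68 A159V records (11.1%, 8.73 to 13.9). All others had bases between the copies, with a median of 60 bp where present in either genotype. In 342 WT and 260 A159V records these bases held a block of 8 or 9 N. Of searched records, 179 of 518 in the WT (34.6%, 30.5 to 38.8) and 148 of 405 in A159V (36.5%, 31.8 to 41.4) had a further stretch of the duplicated segment between the copies. With segments exchanged at random between records, at most 14 of the 923 searched records did so in 1000 draws. Simple repeats made up 46.7% of exact copies in the WT (36.1 to 57.5) and 55.9% in A159V (43.3 to 67.9), against 25.6% (22.4 to 29.0) and 24.6% (21.1 to 28.5) of the other records. Exact copies alone numbered 52 in the WT tumor and 33 in the A159V tumor, a ratio of 0.635 (0.397 to 1.00).

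**Figure D2:**
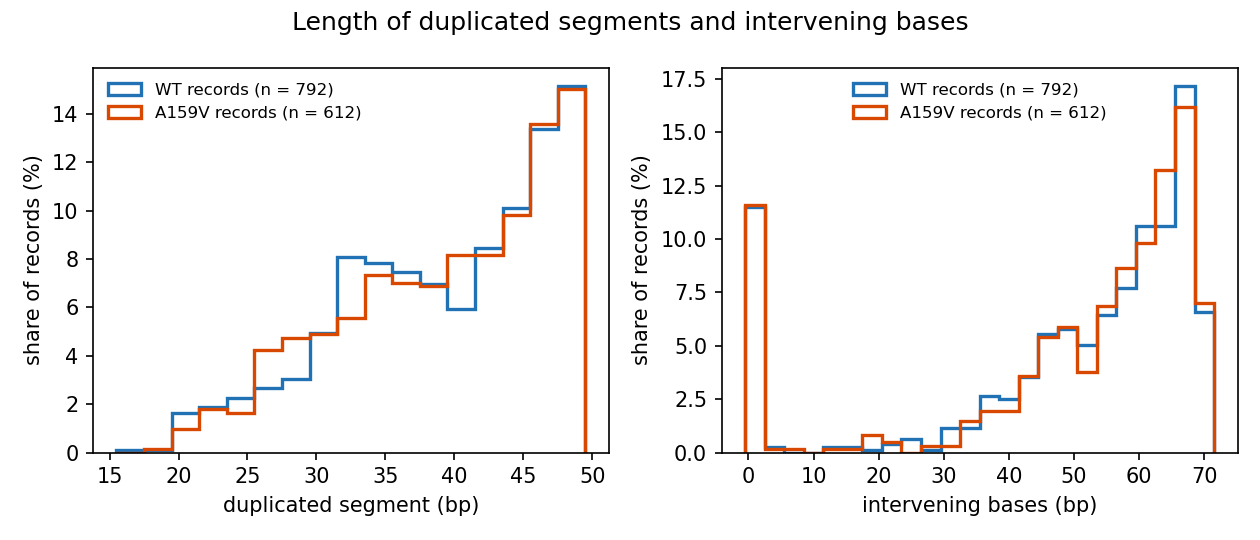
Distribution of the duplicated segment (left, bp) and of the intervening bases (right, bp) as a share of the records of each genotype (vertical axis, %). Lines for the 792 WT and 612 A159V records lie close together; segments stop at 49 bp and intervening bases at 69 bp, with a separate group of exact copies at 0 bp.

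The design asked about coding regions. Protein-coding gene spans held 402 of 792 WT records (50.8%, 47.2 to 54.3) and 343 of 612 A159V records (56.0%, 52.0 to 60.0). No annotated gene overlapped 40% of WT and 36.4% of A159V records. Inserted lengths that were multiples of 3 bp, which would keep a reading frame if they lay in coding exons, made up 40.3% of WT records in gene spans (35.5 to 45.3) and 45.8% of A159V records (40.4 to 51.2), against 33.3% for evenly spread lengths. Outside any annotated gene the shares were 37.2% (31.9 to 42.8) and 41.3% (34.7 to 48.0). Without loci recorded in both genotypes the gene-span shares were 35.7% (30.5 to 41.2) and 42.2% (36.2 to 48.3). Exons were not resolved, so these are shares of gene spans and not of coding sequence.

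The genes with the most records in A159V, Chl1 and Rpap3, were also among the 4 named for the WT. Chl1 held 12 records in each, all between 103649058 and 103649272 on chromosome 6. This was a dense window, and 2 of its 24 records matched major satellite. Median depth at its records was 378.5 reads in WT normal lung, 582 in WT tumor, 287 in A159V normal lung and 373.5 in A159V tumor. Over all sites the medians were 1 to 2 reads. Other satellite families were not screened, so reads from repeat copies elsewhere cannot be told apart from Chl1 itself. Rpap3, which encodes a protein associated with RNA polymerase II, held 4 in the WT and 7 in A159V. Mast4 and Slc6a13 followed in the WT with 4 each, and Cmya5 and Dnah12, a dynein heavy chain gene, in A159V with 3 each, where other genes also had 3. Records also piled up in gene-free windows between 98662783 and 98667332 of chromosome 2 (61 records) and between 3000068 and 3037411 of chromosome 9 (51 records), where 53 and 51 matched major satellite. Satellite records numbered 78 in the WT (9.85%, 7.86 to 12.1) and 51 in A159V (8.33%, 6.27 to 10.8). Multigene families held 39 WT and 32 A159V records.

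The next question was which duplications were particular to a genotype. The same position and variant appeared in both tables for 19 records, and 94 loci had records in both within 10 bp, 73 of them outside dense windows. Of the 15 WT records with 5 or more reads over both libraries, 13 were at loci recorded in A159V too, and of the 10 such A159V records all 10 were at loci recorded in the WT. Among shared loci outside dense windows, 24 had 5 or more reads, 16 of these had reads in both normal lungs, and 9 had reads in all 4 libraries.

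Of the 7 best supported shared loci, Chl1, Irak4, Rpap3, Chsy3 and Igh had the plotted segment duplicated in all 4 libraries. At Cmya5 (none of 61 reads) and Slc6a13 (none of 1 read) the plotted duplication was not seen in A159V tumor. At Chl1 (103649106 to 103649152) it was in 8.92% of 415 reads in WT normal lung (6.36 to 12.1), 7.04% of 625 in WT tumor (5.16 to 9.34), 6.29% of 302 in A159V normal lung (3.83 to 9.65) and 7.05% of 397 in A159V tumor (4.74 to 10). At Rpap3 (chromosome 15, 97686398 to 97686431) an exact copy of the 33 bp segment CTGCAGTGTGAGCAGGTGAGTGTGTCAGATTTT was in 19%, 38.5%, 31.6% and 30.4% of reads in the same order, at depths of 19 to 26 reads. At Irak4 (chromosome 15, 94563065 to 94563088) the 23 bp segment GAACCTCAACTACTGGTTAGTAA was duplicated in 26.7%, 70.0%, 55.0% and 42.1% of reads, at depths of 15 to 20. At Chsy3, a chondroitin synthase gene (chromosome 18, 59303486 to 59303513), all reads in each library carried the duplication, 2, 6, 4 and 3 reads. In the immunoglobulin heavy chain locus Igh (chromosome 12, 114804995 to 114805030) the share was between 3.33% and 7.84%. Of the variants identical in both tables, the 6 with most reads in protein-coding gene spans lay in Rpap3, Cmya5, Mast4 and C2cd2l. At Chl1, Irak4, Slc6a13, Chsy3 and Igh the duplicated segment was the same in both genotypes, but the intervening bases were not identical.

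**Figure D3:**
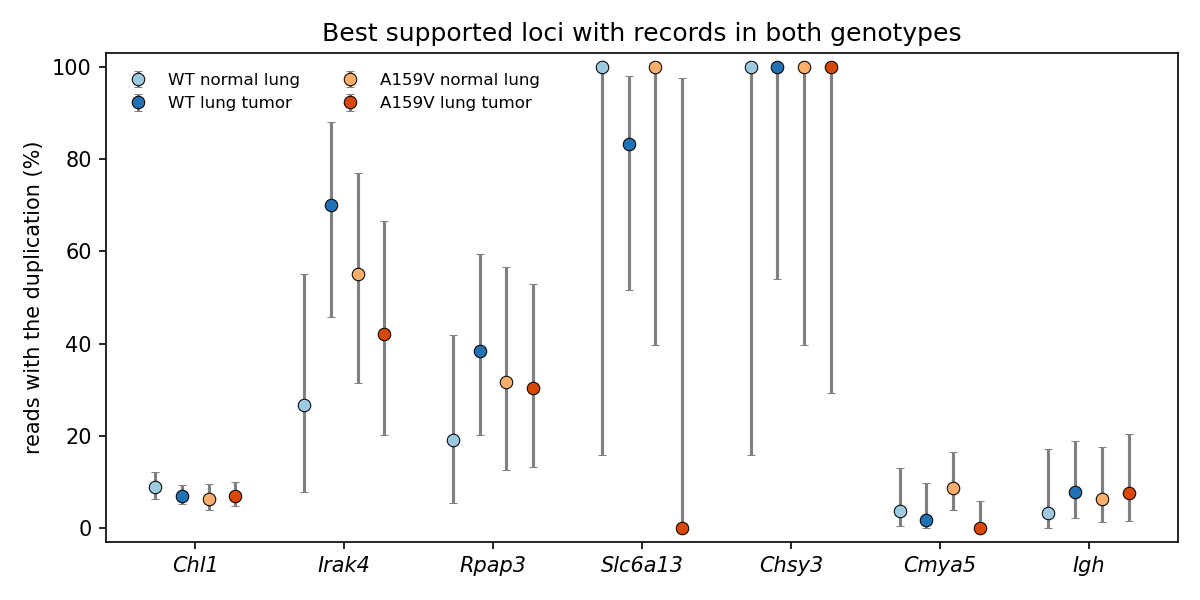
Share of reads that carried the duplication (vertical axis, %) at the 7 best supported loci with records in both genotypes, for each of the 4 libraries, with Clopper-Pearson 95% intervals as error bars. Chl1 lies between 6.29% and 8.92% in all libraries, Chsy3 at 100% in all, and the intervals of the libraries overlap at every locus.

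Over all calls the median variant read fraction was 50% in each library, since 54.8% to 58.7% of calls had at most 1 reference read. With at least 20 reads at the site it was 1.30% in WT normal lung (0.806 to 2.44, 83 calls), 0.919% in WT tumor (0.521 to 1.47, 124 calls), 1.51% in A159V normal lung (1.00 to 2.17, 70 calls) and 0.855% in A159V tumor (0.288 to 1.75, 81 calls). The largest fraction at such depth was that of Irak4 in the WT tumor, 70.0%. Intervals overlapped between the genotypes and between the tissues. Since 87.5% to 92.7% of all calls rested on 1 read, a low fraction can reflect high depth. With at least 20 reads in both libraries, 45 of 78 WT normal and 59 of 114 WT tumor calls lay outside dense windows. In A159V these were 50 of 65 and 35 of 72. The medians thus mix satellite and other sites in unlike shares.

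Lung cancer genes held 7 of 402 WT gene-span records (1.74%, 0.703 to 3.55) and 4 of 343 in A159V (1.17%, 0.319 to 2.96), where their share of gene length was 1.25%. Fgfr2 had 2 records in each genotype at the same start; in A159V each had 1 normal read and no tumor read. Erbb3, a receptor tyrosine kinase, had 1 of 33 reads in WT normal lung and none of 35 in the tumor. Alk, a receptor tyrosine kinase, had 2 WT records and 1 in A159V, Ptprd, a receptor phosphatase, had 2 in the WT, and Arid1b, a chromatin remodelling subunit, had 1 in A159V, each with 1 read.

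Replication genes held 4 WT records (0.995%, 0.272 to 2.53) and 2 in A159V (0.583%, 0.0707 to 2.09), against 0.231% of gene length. They were in Mcm8, a helicase of homologous recombination found in both genotypes, in the WT genes Ticrr, Blm and Gins1, and in the A159V gene Recql4. Mcm8 had 2 of 2 A159V tumor reads and 1 of 2 WT tumor reads, and Ticrr had 1 of 72 WT tumor reads (1.39%, 0.0352 to 7.5). DNA repair genes held 3 WT records (0.746%, 0.154 to 2.17), all at the same start in Fanca, and 5 in A159V (1.46%, 0.475 to 3.37), in Fanca, Fanci, Nhej1, Parp1 and Msh4, against 0.549% of length. Fanca and Fanci belong to the Fanconi anaemia pathway of crosslink repair, and Nhej1 acts in end joining. Each had at most 1 read per library.

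The other lists held few records. Large genes had 4 in the WT (Dnah12, Neb, Ttn and Zfhx3) and 8 in A159V, 3 of them in Dnah12, where their length would give 7.61 and 6.49. Chromatin genes had 3 in the WT (Chd3, Chd6 and Kat2b) and 1 in A159V (Setd1a), against 2.20 and 1.88 by length. RAS, MAPK and PI3K signalling had 3 in the WT (Ddr2 and 2 in Epha5) and 1 in A159V (Igf2r), against 1.96 and 1.67. Polyglutamine genes had 2 in the WT (Arid3b and Mef2a) and 1 in A159V (Arid1b), against 2.27 and 1.94. Apoptosis and cell cycle genes had 0 in the WT and 2 in A159V (Birc6 and Rbl2), against 0.812 and 0.693. Genes of lung epithelium and secreted products had 0 in both, against 0.279 and 0.238. The WT interval of replication genes lay above their share of gene length, but its 4 records had 1 read each, captured exon length was not used here as a baseline, and the intervals were not adjusted for the 18 shares.

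**Figure D4:**
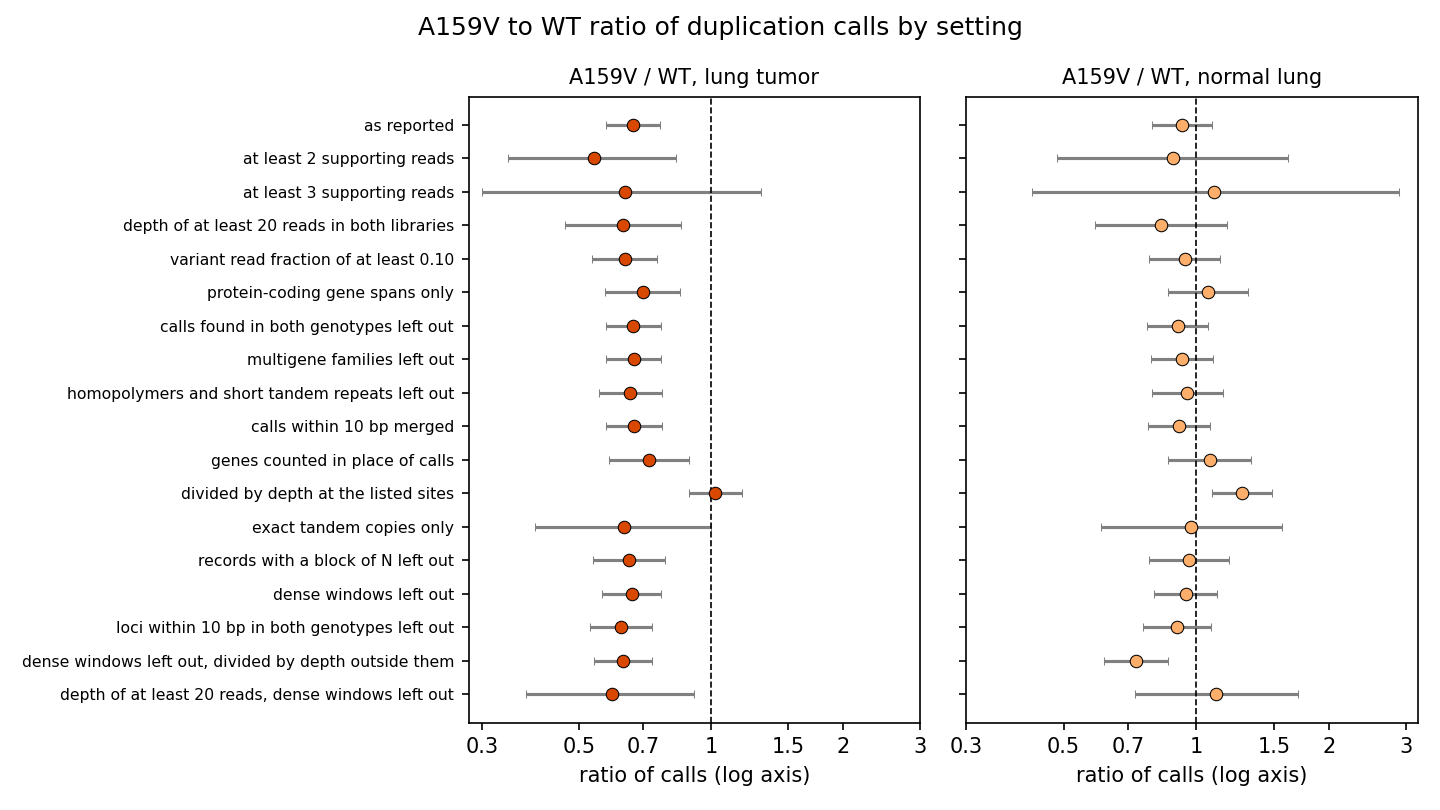
Ratio of A159V to WT calls (horizontal axes, log scale) for lung tumor (left) and normal lung (right) as reported and under the alternative settings, with exact conditional 95% intervals as error bars and a dashed line at 1; the setting of 5 reads is not drawn. The tumor ratio lies below 1 in all settings drawn except division by the reads at each genotype's own recorded sites, where it is 1.02.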

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

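All tests of explanations in this part were chosen after the result was seen.

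The A159V tumor library held fewer calls than the WT tumor library, and the tumor to normal ratio of calls differed between the genotypes by a factor of 0.684 (0.545 to 0.858). Depth was compared at 15 of the 71 loci called in both genotypes outside dense windows and satellite. These 15 had at least 40 reference reads in all. There the mean log2 A159V to WT depth ratio of the tumors was -0.0055 (-0.22 to 0.21). At 22 loci with at least 10 reads it was -0.11 (-0.34 to 0.13), against -0.59 (-0.79 to -0.39) for the calls. Depth at these loci was thus lowered less than the calls, if at all. The loci were chosen for records in both genotypes and for coverage, which favours similar depth. Lower depth at the poorly covered sites that hold most calls was not tested and stays open. Satellite arrays and other dense windows were left out and the ratio stayed at 0.660 (0.565 to 0.769), and the factor between the tumor to normal ratios at 0.672 (0.528 to 0.854), or 0.832 (0.654 to 1.06) when also scaled by reads outside these windows. Fewer off-target reads in A159V may contribute and cannot be told apart from the genotype. At 16 satellite positions recorded in both genotypes A159V tumor depth was 0.715 times the WT depth (0.687 to 0.725), near the call ratio. In normal lung it was 0.744 times (0.666 to 0.756), below the call ratio of 0.929. These positions were not merged into loci, so neighbours can share reads and the intervals can be too narrow. A difference between genotypes or between animals remains open and untested, with 1 library per group.

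Records that held the reverse complement of the duplicated segment between the copies numbered 34 of 923 searched, 24 in the WT (4.63%, 2.99 to 6.82) and 10 in A159V (2.47%, 1.19 to 4.49), signals in inserted bases that the comparisons do not use. Chance similarity was tested by exchanging segments between records, which gave at most 13 such records in 1000 draws, mean 4.44. Fold-back molecules made in library preparation or sequencing are a candidate source that stays open, since 5.88% of these records (2 of 34; 0.720 to 19.7) had 2 or more reads, against 15.4% (13.1 to 18) of the other searched records. Of the 34 records, 22 lay in protein-coding gene spans, such as Rbl2 and Cd2bp2 in A159V and Vmn2r43 and Acot12 in the WT. None of the 34 was at a locus recorded in both genotypes. The genes named here were chosen after their values were seen. No biological explanation was tested, since the intervals of the 2 genotypes overlap.

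Reference reads at major satellite sites were 2.0 times as many in the tumor as in normal lung of the WT (median over 41 loci, 1.87 to 2.10) and 1.86 times as many in A159V (29 loci, 1.73 to 2.01). Outside dense windows the same ratios were 1.05 (1.00 to 1.11, 103 loci) and 1.05 (0.969 to 1.13, 82 loci). A block of 8 or 9 N lay in the intervening bases of 602 records, 43.2% in the WT (39.7 to 46.7) and 42.5% in A159V (38.5 to 46.5).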

How the results depend on the processing

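Settings added after the data were seen were exact copies alone, records with N left out, dense windows left out with or without scaling, depth outside dense windows, shared loci left out, and, for the gene-span share, depth. No paired analysis was possible because each group has 1 library. The lower A159V tumor count had a ratio below 1 in 17 of 18 alternatives, in 14 with an interval below 1. The A159V to WT ratio of the tumor to normal ratios was below 1 in all 17 alternatives that gave it, in 12 with an interval below 1. At 5 reads the WT tumor to normal ratio could not be formed, since no call was in normal lung alone. The share in coding sequence by the reference annotation was not run apart, since it is the value reported. The number of sites past the Fisher threshold was 0 under each setting. Stricter settings count fewer records; beyond that, the cause was not tested.

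Counts are given in the order WT normal lung, WT tumor, A159V normal lung, A159V tumor. They were 26, 63, 23 and 34 at 2 reads, 10, 22, 11 and 14 at 3 reads, and 1, 8, 4 and 5 at 5 reads. They were 78, 114, 65 and 72 at depth 20, and 45, 59, 50 and 35 at that depth without dense windows. In protein-coding spans they were 179, 253, 190 and 177; as genes 166, 219, 178 and 158; as exact copies 39, 52, 38 and 33; without N blocks 188, 289, 181 and 188. Divided by depth, A159V normal lung came to 486 calls.

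Division by reads summed over each genotype's own sites, most of them satellite reads, reversed the A159V to WT tumor ratio to 1.02 and the WT tumor to normal ratio to 0.925. The sites differ between genotypes, so across genotypes this is no depth correction. It moved the A159V to WT ratio of normal lung to 1.27 and the A159V tumor to normal ratio to 0.713. With dense windows left out and such sums taken outside them, the normal lung ratio was 0.731, the WT tumor to normal ratio 1.20, the A159V to WT tumor ratio 0.631 (0.541 to 0.735) and the ratio of ratios 0.832 (0.654 to 1.06), against 0.672 (0.528 to 0.854) unscaled. The A159V to WT tumor ratio moved to 0.540 at 2 reads. That of normal lung moved to 1.10 at 3 reads, 4 at 5 reads (0.396 to 197), and 1.11 at depth 20 without dense windows. The WT tumor to normal ratio moved to 3.64 at 2 reads, 3.40 at 3 reads and 1.34 for exact copies. The A159V tumor to normal ratio moved to 1.73, 1.6 and 2 at 2, 3 and 5 reads, 0.871 for genes, 0.857 for exact copies and 0.659 at depth 20 without dense windows. The ratio of these ratios moved to 0.479 at 2 reads, 0.481 at 3 reads and 0.490 at depth 20 without dense windows.

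The median length moved to 35 bp in the WT at 5 reads, and to 37.5 bp in the WT and 36 bp in A159V for exact copies. The in-frame share rose to 75% (34.9 to 96.8) in both genotypes at 5 reads, and the gene-span share to 80.0% (44.4 to 97.5) in A159V. These rest on few records, 15 in the WT and 10 in A159V before the limit to gene spans. Of these, 13 and 10 were at loci recorded in both genotypes, so the 2 shares are not independent. Median read fractions moved to 1.30%, 0.919%, 1.51% and 0.855% at depth 20. Shared sites numbered 94 within 10 bp and 1 at 5 reads. Counting each call, as in the Results, in place of genes with a call moved the WT lists from 1 to 3 for DNA repair. For lung cancer the WT list moved from 4 to 7. At 5 reads the lung cancer list kept 1 gene in the WT, and all other lists held 0.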

Other observations

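Of the tests in this part, the chance test was fixed before its result was seen and the other one after.

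Satellite arrays were a separate group of sites. They held 58 calls in the WT tumor (44.0 to 75), 38 in the A159V tumor (26.9 to 52.2), 30 in WT normal lung (20.2 to 42.8) and 16 in A159V normal lung (9.15 to 26.0). Per 10000 reads summed over these records, 5.90 supported a duplication in the WT tumor (4.70 to 7.33) and 5.68 in the A159V tumor (4.22 to 7.49). In WT normal lung 3.95 did (2.68 to 5.60) and in A159V normal lung 3.39 (2.01 to 5.36), with overlapping intervals. Many records overlap, so the same reference reads were summed more than once, and the intervals wrongly treat them as independent. The sites were each genotype's own and were recorded for having a duplicated read. The values are therefore not rates over satellite DNA and do not compare the genotypes. Some shared loci with 5 or more reads overlapped no annotated gene. The regions near position 59959366 of chromosome 19 and 119025401 of chromosome 7 were among these. Atf7ip, Zfp236, Mib1 and Sema5a were among those in genes.

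For loci recorded in both genotypes, the same position by chance was tested by shifting A159V loci at random along their chromosomes. This gave at most 1 shared locus outside dense windows in 1000 draws, against 73 seen. The shifts took no account of capture, coverage or sequence. They therefore cannot tell how much sharing comes from calls that gather at the same kinds of site. A difference from the reference genome carried by all tissues of both genotypes, such as a strain variant or an unassembled copy of the region, stays open. It predicts reads in every library that covers the site well. Of the 24 well-supported shared loci, 100% (85.8 to 100) had reads in a normal library, but their choice by reads pooled over the libraries favours this. Both normal lungs had reads at 16 of the 24 (66.7%, 44.7 to 84.4), all 4 libraries at 9, and Cmya5 had none of 61 A159V tumor reads. Depth limits these counts, since some loci had almost no reads in a library. WT normal lung had a depth of 0 at the Fgfr2 and Sucla2 records, and A159V tumor a depth of 2 at C2cd2l. Missing reads at such depths cannot show absence. Of all 73 loci 60 had reads in a normal library (82.2%, 71.5 to 90.2), and 13 with at most 4 reads each, Slc11a2 and Mcm8 among them, had reads in tumors alone.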
